A study of Homo sapiens with 12 samples.

How the data were processed

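RNA sequencing of 12 libraries from the mesothelioma line MSTO-211H was analysed from 1 table of FPKM (reads scaled to gene length and to the library). Per the labels, total RNA was extracted with Trizol and RNeasy columns, libraries were made with the NEBNext Ultra RNA kit, and they were sequenced on a NovaSeq6000. The genome build was hg38, per the submitters' processing notes; the aligner, the counting tool, its use of strand and the library scaling are not given in the sources used here. The authors deposited FPKM for 58735 genes, with Ensembl identifiers, symbols, biotypes and hg38 coordinates, and other columns gave the gene length in bases that the authors divided by. Coordinates are given as in that table, counted as it counts them.

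Each deposited FPKM times the gene length was a whole multiple of 1 step per library in 100% of values above 0 (tolerance 0.01 of a read), so the values came from whole reads, which were recovered. They summed to 13188257 to 18630958 per library. The per-million values summed to 954758 to 1054110, so the authors' library scaling was not the plain total of these genes. A gene of 1 kb at 1 FPKM rests on 13.3 to 19.1 reads. In all, 1566 symbols belong to more than 1 gene identifier. Tests used identifiers, and the values of a named gene are those of the first with its symbol. Genes that share sequence with copies, such as ribosomal protein genes, FTH1 and HSD17B7, and genes that overlap, such as KRT8 and KRT18, can share reads, and their values are uncertain to that extent. Of the tested genes, 429 are under 200 bases, where few reads give large FPKM. No other value column was left without a sample (0).

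Groups came from the sample titles (Con, IR, Rx, Combo) and replicate numbers likewise. Replicates were compared by a chi-square of their recovered reads, and none was a repeat of another.

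Expression was taken as log2(FPKM + 1) for genes with a mean of at least 1 FPKM over the 12 libraries (13038 genes, 10751 of them protein-coding). Group means were fitted with limma 3.58.1 in R 4.3.3, with a variance trend, two-sided moderated tests and Benjamini-Hochberg adjustment (threshold 0.05), with all 12 libraries sharing 1 estimate of the spread. Fold changes are on the log2(FPKM + 1) scale, which understates those of low genes. There were 6 planned comparisons, 5 between groups and the interaction. Of 26 gene lists fixed before the data were examined, 23 had at least 5 measured genes and were tested with limma's camera at a preset correlation of 0.01. Camera with a correlation estimated from the data called 0 lists in every comparison, and its adjusted p stands beside each call. Limma's fry, which asks whether a list moves one way without comparing it with other genes, called 2 lists in IR against Con (p53 targets, lysosome), 0 in Rx against Con, 8 in Combo against Con, 0 in the other planned comparisons, 6 with QTP averaged and 2 with radiation averaged. Counts adjusted over the list alone come from the same gene tests, so they add no separate support to a list call. Members that move together tend to pass or fail together.

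Genes were named by a rule fixed at the same time. It takes the largest changes past the threshold with non-overlapping groups (none in the planned comparisons), up to 3 members with the smallest p of each called list in its direction, and always a fixed set that includes CDKN1A, MDM2, HMGCS1, INSIG1, MKI67 and DRD1 to DRD5; the rest of that set is not reported here. All 12 genes past the threshold with QTP averaged were named; for that comparison, and for levels of other receptors, markers and hypoxia genes (HTR1D, HRH1, MAOA, MSLN, CD44, SOX2, CA9, LDHA, PFKFB3), names were chosen after their values were seen.

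After the data had been examined, comparisons averaged over both arms of the other treatment were added, as were exact permutations of list means per library within arms (400 arrangements, 46 tests), limma voom on the recovered reads, a fit of protein-coding genes alone, and a fit without IR 3 and Combo 3. Voom called 0 genes in the 6 planned comparisons and 33 with QTP averaged. Alternatives planned before were another pseudocount (0.1), no filter or a mean of at least 5 FPKM, rescaling to TPM, by the median of ratios or by quantiles, only the groups compared in the fit, no variance trend, library quality weights, the replicate number as a block, and each library left out in turn.

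The gene test was tested on simulated data for Combo against Con over 12901 genes. It recovered 24 of 67 genes changed 1.5-fold, 49 of 67 changed 2-fold and 59 of 66 changed 4-fold, in 141 calls, of which 5 were false and 4 were members of the shifted list described next. Camera gave a simulated list of 25 genes shifted by 0.3 a p of 2.27e-16 and an unchanged list a p of 0.693. The simulated genes were drawn independently, so this cannot show how camera behaves for lists whose members move together. Nor can it show what share of changed genes limma recovers where many genes of a library deviate together. A single unchanged list also gives no rate of false calls. A comparison of 3 libraries with 3 has a smallest exact p of 0.1. Figures were drawn with matplotlib 3.10.9.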

Results

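RNA was sequenced from MSTO-211H, an established human mesothelioma line, grown in suspension in medium with growth factors; the submitters call the cells mesothelioma-initiating. Cells received vehicle or 10 µM of a compound that the labels name only QTP, and the next day 4 Gy or a sham exposure. RNA was taken 48 h after irradiation. The series title speaks of combining dopamine receptor inhibition with radiotherapy, so the design asks what each treatment does alone and what they do together. There were 4 groups of 3 libraries: Con (vehicle, sham), IR (vehicle, 4 Gy), Rx and Combo. The design text has 4 arms and the other titles account for 3 of them, so Rx was read as QTP with sham exposure and Combo as QTP with 4 Gy. Nothing in the labels says that the libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

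The deposited values were FPKM per gene, and whole reads recovered from them gave 13188257 to 18630958 per library. The group means were 15216794 ± 1757178 reads for Con, 14861985 ± 722160 for IR, 17253387 ± 2019535 for Rx and 18109511 ± 608132 for Combo (SD, n = 3), so the QTP groups were the deeper ones. Mitochondrial genes took 7.79 ± 1.29% of reads in Con, 8.50 ± 1.90% in IR, 9.08 ± 0.62% in Rx and 8.70 ± 0.55% in Combo (SD, n = 3). Library IR 3 had the highest mitochondrial share (10.5%) and the fewest genes above 0 (23102). On the first principal component, with 26.5% of the variance, IR 3 and Combo 3 lay at opposite ends (28.7 and -21.5). No replicate pair was a repeat of 1 library, since the chi-square per degree of freedom between replicates was 7.84 to 44.8.

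DRD4 was the only dopamine receptor gene above the filter of a mean of 1 FPKM (chromosome 11, 637293 to 640706, hg38). It averaged 4.11 ± 0.698 FPKM in Con, 4.44 ± 1.14 in IR, 4.35 ± 1.09 in Rx and 3.84 ± 0.63 in Combo (SD, n = 3), from 71 to 145 reads per library. DRD1 had at most 2 reads, in 2 libraries, and DRD2 at most 2 reads, in 1 library. DRD3 and DRD5 had 0 reads in all 12 libraries. A count of 0 allows up to 3 reads per library, which is at most 0.108 FPKM for DRD3 and 0.0971 for DRD5, for counting error only. Of other receptors that antipsychotic drugs bind, 3 of 18 passed the filter and 11 averaged under 0.1 FPKM. HTR1D averaged 15.5 FPKM and HRH1 3.45. The dopamine list had 4 measured genes and the list of other receptors 3, too few to test. MAOA, which breaks down dopamine, averaged 1.46 FPKM.

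Of 16 mesothelial markers 6 passed the filter and 5 averaged under 0.1 FPKM, and of 20 stem and initiating cell genes 9 passed and 8 averaged under 0.1. The mesothelial surface gene MSLN averaged 40.1 FPKM and the adhesion receptor gene CD44 44.3. SOX2, a pluripotency factor gene, had at most 1 read, in 2 libraries. Of 16 markers of immune, endothelial and fibroblast cells, 14 averaged under 0.1 FPKM and 1 passed the filter. None of the 9 measured stem and initiating cell genes passed limma's test in any comparison. Limma called 0 of all 13038 tested genes in each planned comparison and 12 with QTP averaged, so this says little about these 9 in particular. Their list was not called in any of the 6 planned comparisons (lowest camera adjusted p = 0.260). The lists for end joining repair (lowest adjusted p = 0.216), immediate early genes (0.0923), mesenchymal and matrix genes (0.0976) and YAP and TAZ targets (0.208) were not called in these 6 either, by the same test.

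No single gene passed an adjusted p of 0.05 in any of the 6 planned comparisons, by limma on log2(FPKM + 1) over 13038 genes with the groups as the only terms. At an unadjusted p under 0.05, limma gave 894 genes in IR against Con, 425 in Rx against Con, 1719 in Combo against Con, 2278 in Combo against IR, 1188 in Combo against Rx and 995 in the interaction. With limma voom on the recovered reads the adjusted counts were also 0, with 847, 410, 1795, 2415, 1374 and 1100 genes at an unadjusted p under 0.05. In data simulated for Combo against Con over 12901 genes, the same test recovered 35.8% of genes changed 1.5-fold, 73.1% of those changed 2-fold and 89.4% of those changed 4-fold. The simulated genes were drawn independently, without differences shared by many genes of a library, so these shares may not hold for the real libraries. Without a filter on low values, limma called 1 to 6 genes in each of the 6 comparisons. With the replicate number as a block, limma did call genes in Combo against Con. Voom with that block also called some in IR against Con and Combo against IR (see the part on processing). What follows rests on gene lists fixed in advance. Splits of the same libraries, the real one included, called as many lists in 5 of 10 for IR against Con and 8 of 10 for Combo against Rx. The share was 1 of 10 for each other comparison between groups. For the interaction it was 97 of 100, but those splits shuffled all 12 libraries over the 4 groups. Effects of either treatment alone can enter such splits, so they cannot decide on chance. Chance is therefore not excluded for the list calls. Values of single genes are descriptive, given as log2 changes with their standard errors.

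**Figure D1:**
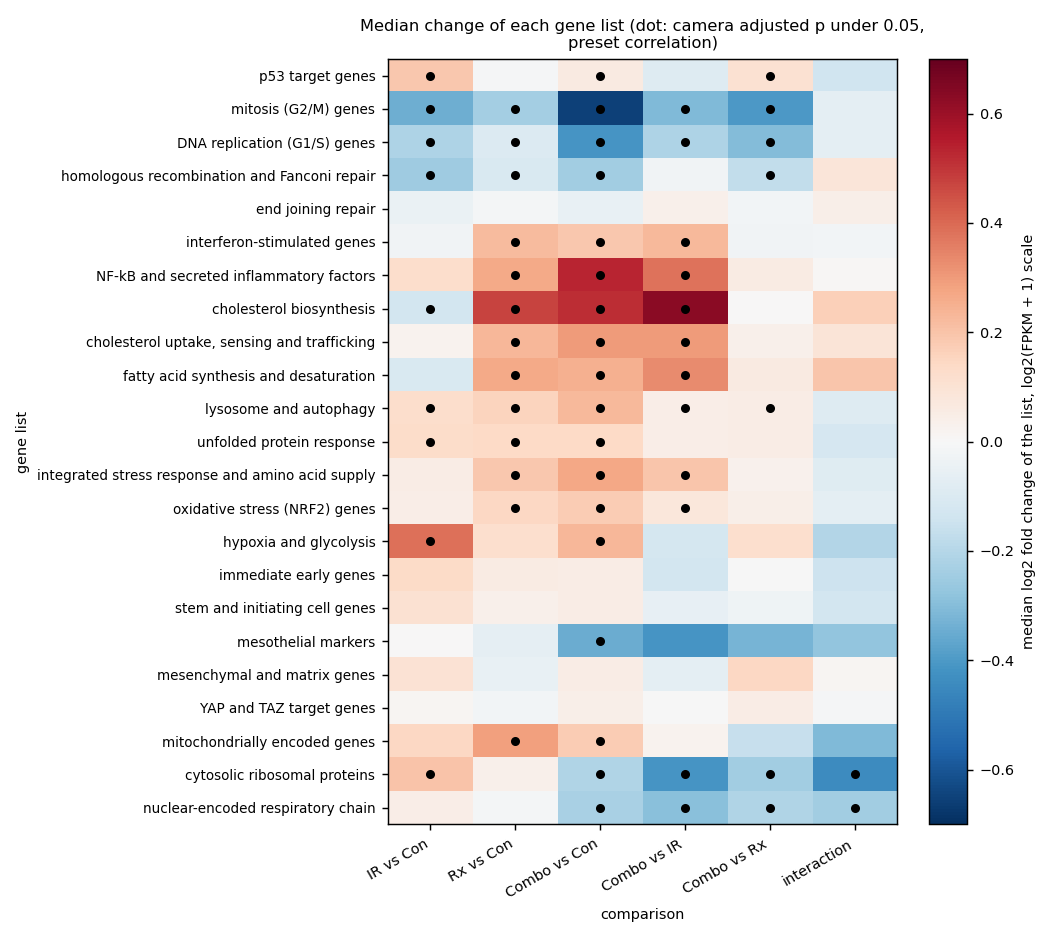
Median log2 change of each of the 23 tested gene lists (rows) in the 5 pairwise comparisons and the interaction (columns), from blue (lower) to red (higher), with a dot where limma's camera test gave an adjusted p under 0.05 with a preset correlation. Cholesterol biosynthesis stands at 0.47 in Rx against Con, 0.51 in Combo against Con and 0.63 in Combo against IR; mitosis genes reach -0.65 in Combo against Con.

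In the comparison of radiation alone (IR against Con), camera with the preset correlation called p53 targets higher and the lists of mitosis, DNA replication and homologous recombination lower. No list was called with an estimated correlation (lowest adjusted p = 0.149), and no single gene passed. CDKN1A, which encodes the cell cycle inhibitor p21 (chromosome 6, 36676460 to 36687339), went from 147 ± 11.4 FPKM in Con to 208 ± 22.3 in IR (SD, n = 3), a log2 change of 0.49 (SE 0.11). BTG2, an antiproliferative p53 target, differed by 0.41 (SE 0.10) and MDM2, the ubiquitin ligase for p53, by 0.31 (SE 0.15). MKI67, a proliferation marker (chromosome 10, 128096659 to 128126385), went from 11.9 ± 1.64 to 6.95 ± 1.99 FPKM (SD, n = 3), a log2 change of -0.73 (SE 0.21). CENPE, a kinetochore motor, differed by -0.54 (SE 0.11) and the repair gene RAD54L by -0.56 (SE 0.16).

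Of 30 p53 target genes, 29 had a higher mean in IR than in Con (median 0.19), and 2 were higher with p adjusted over the list alone (CDKN1A and BTG2), against 0 with limma over all genes. The camera adjusted p was 7.82e-12, and adjusted p = 0.149 with an estimated correlation. All 28 mitosis genes were lower (median -0.34, 5 adjusted over the list alone; camera adjusted p = 3.17e-16, and adjusted p = 0.338 with an estimated correlation). DNA replication genes had a median of -0.22 (0 adjusted over the list alone; camera adjusted p = 4.80e-08, and adjusted p = 0.580 with an estimated correlation). Homologous recombination and Fanconi genes had one of -0.25 (2 adjusted over the list alone; camera adjusted p = 9.13e-07, and adjusted p = 0.218 with an estimated correlation), a call that ended at a mean of at least 5 FPKM (-0.07, camera adjusted p = 0.0503). Lysosome and autophagy genes rose by a median of 0.12, with CTSB, a lysosomal protease gene, at 0.43 (SE 0.15); none of the 27 passed adjusted over the list alone (camera adjusted p = 1.45e-07, and adjusted p = 0.159 with an estimated correlation). The unfolded protein response list rose by 0.13 (camera adjusted p = 8.39e-04, and adjusted p = 0.218 with an estimated correlation).

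Cytosolic ribosomal protein genes were also higher (median 0.20; camera adjusted p = 8.74e-08, and adjusted p = 0.580 with an estimated correlation), as were hypoxia and glycolysis genes (0.39; camera adjusted p = 0.00199, and adjusted p = 0.580 with an estimated correlation). Cholesterol biosynthesis genes were lower (-0.13; camera adjusted p = 0.00439, and adjusted p = 0.622 with an estimated correlation). In these 3 lists 0 genes passed adjusted over the list alone. Leaving out 1 library ended these calls: for ribosomal genes without IR 3 (0.06, camera adjusted p = 0.0800), for hypoxia without Con 3 (0.04, 0.809) or IR 1 (0.28, 0.262), and for cholesterol without Con 2 (-0.04, 0.177) or IR 1 (-0.15, 0.0642). Without Con 1 the hypoxia median was 0.70, without IR 1 the ribosomal one 0.35, without Con 3 the cholesterol one -0.26, without Con 2 that of DNA replication -0.10, without IR 3 that of homologous recombination -0.16 and that of the unfolded protein response 0.07. Limma called 3 genes without IR 1 and 1 without Rx 2 or Rx 3, in place of 0.

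For QTP alone (Rx against Con), camera with the preset correlation called cholesterol biosynthesis and the lists of neighbouring pathways higher. With an estimated correlation 0 lists were called (lowest adjusted p = 0.0532), fry called 0, and no single gene passed. HMGCS1, the enzyme that makes HMG-CoA (chromosome 5, 43289395 to 43313512), was at 21.1 ± 4.75 FPKM in Con and 38.7 ± 16.6 in Rx (SD, n = 3), a log2 change of 0.79 (SE 0.28). DHCR7, which makes cholesterol in the last step, differed by 0.75 (SE 0.20). INSIG1, a sterol-regulated gene of the SREBP pathway, differed by 1.01 (SE 0.39), from 31.8 ± 10.5 to 71.0 ± 44.9 FPKM (SD, n = 3). CDKN1A differed by 0.19 (SE 0.11) and MDM2 by -0.02 (SE 0.15), and the p53 list was not called (median -0.01, camera adjusted p = 0.966).

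Of 21 cholesterol biosynthesis genes, 19 were higher in Rx (median 0.47), and 16 were so adjusted over the list alone, against 0 with limma over all genes. The camera adjusted p was 4.31e-22, and adjusted p = 0.0821 with an estimated correlation. Fatty acid synthesis and desaturation genes rose by a median of 0.27, 16 of 16 having a higher mean (3 adjusted over the list alone; camera adjusted p = 2.77e-11, and adjusted p = 0.118 with an estimated correlation). Examples are FADS1, a fatty acid desaturase gene, at 0.43 (SE 0.11), and ACLY, which makes cytosolic acetyl-CoA, at 0.41 (SE 0.12). Cholesterol uptake and trafficking genes rose by 0.23 (1 adjusted over the list alone, STARD4, which carries sterols between membranes; camera adjusted p = 6.92e-09, and adjusted p = 0.0911 with an estimated correlation). Without Rx 2 the medians of cholesterol biosynthesis and fatty acid synthesis were 0.30 and 0.14.

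Lists of cell stress rose by smaller amounts. The medians were 0.19 for the integrated stress response (camera adjusted p = 1.22e-10, and adjusted p = 0.0532 with an estimated correlation), and 0.15 for lysosome and autophagy genes (camera adjusted p = 2.25e-11, and adjusted p = 0.0532 with an estimated correlation). They were 0.14 for NRF2 genes (camera adjusted p = 5.71e-06, and adjusted p = 0.0754 with an estimated correlation) and 0.14 for the unfolded protein response (camera adjusted p = 2.77e-06, and adjusted p = 0.0754 with an estimated correlation). Adjusted over the list alone, 1 unfolded protein response gene (XBP1, 0.37, SE 0.10) and 0 of the other 3 lists passed. NF-kB and secreted factors had a median of 0.27 (camera adjusted p = 3.89e-07, and adjusted p = 0.171 with an estimated correlation), with the chemokine gene CXCL2 at 1.08 (SE 0.24) and the only one adjusted over the list alone. Mitochondrially encoded genes had 0.29 (camera adjusted p = 1.09e-05, and adjusted p = 0.337 with an estimated correlation) and interferon-stimulated genes 0.22 (camera adjusted p = 4.60e-04, and adjusted p = 0.505 with an estimated correlation).

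Proliferation genes were lower after QTP alone too. All 28 mitosis genes had a lower mean (median -0.24; camera adjusted p = 8.31e-14, and adjusted p = 0.249 with an estimated correlation), as did 24 of 27 replication genes (-0.09; camera adjusted p = 3.26e-05, and adjusted p = 0.505 with an estimated correlation) and 15 of 16 recombination genes (-0.11; camera adjusted p = 8.98e-04, and adjusted p = 0.292 with an estimated correlation). None passed adjusted over the list alone. Calls ended without Con 2 (replication -0.01, camera adjusted p = 0.699; recombination -0.07, 0.104; interferon 0.06, 0.265), without Rx 3 (replication -0.01, 0.744), without Rx 2 (recombination -0.05, 0.0765), at a mean of at least 5 FPKM (recombination -0.08, 0.0582) and without Rx 1 (interferon 0.12, 0.125). The mitosis median was -0.09 without Rx 3 and -0.14 without Con 2, that of replication -0.15 without Con 1, -0.17 without Con 3 and -0.19 without Rx 1, and without Rx 3 that of the integrated stress response was 0.29 and that of NF-kB 0.46 (0.44 without Con 1).

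**Figure D2:**
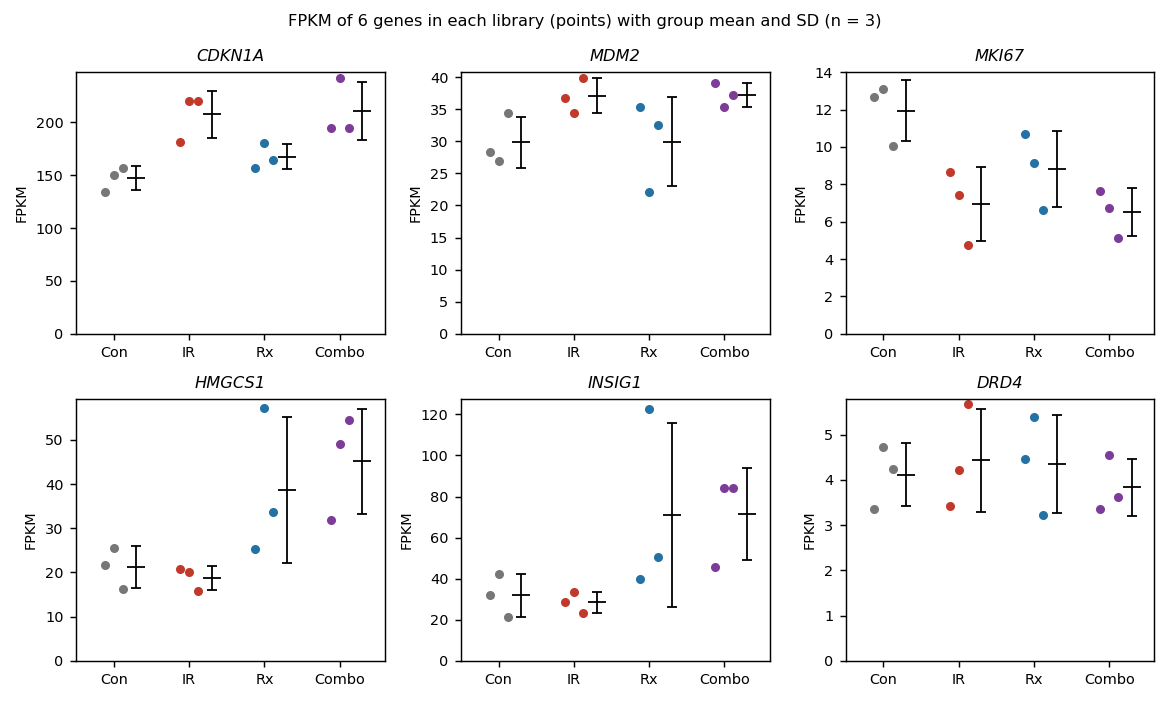
FPKM (vertical axes, from 0) of 6 genes named in advance, in each library of the 4 groups (points), with the group mean and SD (black, n = 3). CDKN1A averages 208 FPKM in IR and 211 in Combo against 147 in Con, HMGCS1 38.7 in Rx and 45.1 in Combo against 21.1 in Con, and DRD4 is between 3.84 and 4.44 in all 4 groups.

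With both treatments together (Combo against Con), camera with the preset correlation called proliferation lists lower and sterol and stress lists higher. None was called with an estimated correlation (lowest adjusted p = 0.0811). Of the mitosis genes, 28 of 28 were lower, by a median of -0.65, and 27 of them adjusted over the list alone (camera adjusted p = 1.31e-26, and adjusted p = 0.168 with an estimated correlation). KIF20A, a mitotic kinesin gene, went from 9.10 ± 1.63 FPKM in Con to 4.35 ± 1.04 in Combo (SD, n = 3), a log2 change of -0.92 (SE 0.18). MKI67 differed by -0.79 (SE 0.21). Replication genes fell by 0.41 on the log2 scale, with 24 of 27 adjusted over the list alone (camera adjusted p = 1.04e-16, and adjusted p = 0.168 with an estimated correlation), among them the replisome gene GINS2 at -0.74 (SE 0.16). Recombination genes had a median of -0.24, with 7 adjusted over the list alone (camera adjusted p = 2.56e-05, and adjusted p = 0.168 with an estimated correlation), a call that ended at a mean of at least 5 FPKM (-0.03, camera adjusted p = 0.597).

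Cholesterol biosynthesis rose by a median of 0.51, with 15 of 21 genes adjusted over the list alone (camera adjusted p = 5.06e-12, and adjusted p = 0.168 with an estimated correlation). HMGCS1 reached 45.1 ± 11.8 FPKM (SD, n = 3; log2 change 1.05, SE 0.28), and SCD, the stearoyl-CoA desaturase gene, went from 123 ± 45.0 to 300 ± 86.4 FPKM (1.31, SE 0.37). Fatty acid synthesis genes rose by 0.25 (6 adjusted over the list alone; camera adjusted p = 2.60e-07, and adjusted p = 0.168 with an estimated correlation). Cholesterol uptake genes rose by 0.30 (3 adjusted over the list alone; camera adjusted p = 5.73e-06, and adjusted p = 0.168 with an estimated correlation), including NPC1, which exports cholesterol from lysosomes, at 0.75 (SE 0.21). Lysosome and autophagy genes rose by 0.23, with 15 of 27 adjusted over the list alone (camera adjusted p = 4.84e-12, and adjusted p = 0.0811 with an estimated correlation). SQSTM1, an autophagy adaptor gene, went from 57.2 ± 6.27 to 81.5 ± 8.76 FPKM (SD, n = 3).

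The integrated stress response rose by 0.27, with 18 of 18 genes higher and 8 adjusted over the list alone (camera adjusted p = 8.41e-08, and adjusted p = 0.132 with an estimated correlation). NRF2 genes rose by 0.18 (5 adjusted over the list alone; camera adjusted p = 3.85e-04, and adjusted p = 0.168 with an estimated correlation), TXNRD1, thioredoxin reductase, being at 0.55 (SE 0.10). The unfolded protein response rose by 0.14 (7 adjusted over the list alone; camera adjusted p = 6.06e-05, and adjusted p = 0.168 with an estimated correlation). NF-kB and secreted factors rose by 0.53 (2 adjusted over the list alone; camera adjusted p = 7.27e-06, and adjusted p = 0.168 with an estimated correlation). The p53 targets rose by 0.06 (6 adjusted over the list alone; camera adjusted p = 2.14e-04, and adjusted p = 0.168 with an estimated correlation), CDKN1A being at 0.51 (SE 0.11) and MDM2 at 0.31 (SE 0.15). The p53 median was 0.03 without Combo 2 and 0.10 without either Combo 3 or Con 3.

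Mesothelial markers fell by a median of 0.34 on the log2 scale over 6 genes, 3 of them adjusted over the list alone (camera adjusted p = 0.0333, and adjusted p = 0.168 with an estimated correlation). These were the calcium-binding calretinin gene CALB2 (-0.73, SE 0.19) and the keratins KRT8 (-0.51, SE 0.16) and KRT18 (-0.48, SE 0.18), whose annotated spans overlap. The call ended without Combo 1 (-0.26, camera adjusted p = 0.0941), Combo 3 (-0.21, 0.0526) or Con 3 (-0.30, 0.0524), and the median was -0.57 without Combo 2. Respiratory chain genes encoded in the nucleus fell by 0.23 on the log2 scale (1 adjusted over the list alone, SDHA of complex II; camera adjusted p = 1.80e-08, and adjusted p = 0.210 with an estimated correlation). Ribosomal protein genes fell by 0.21 on that scale (0 adjusted over the list alone; camera adjusted p = 1.40e-06, and adjusted p = 0.478 with an estimated correlation), with -0.14 without Combo 3.

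Weaker calls in Combo against Con, with 0 genes adjusted over the list alone, were hypoxia (0.23; camera adjusted p = 0.00753, and adjusted p = 0.594 with an estimated correlation), interferon-stimulated genes (0.19; camera adjusted p = 0.0243, and adjusted p = 0.603 with an estimated correlation) and mitochondrially encoded genes (0.18; camera adjusted p = 0.0333, and adjusted p = 0.603 with an estimated correlation). Hypoxia turned to -0.04 without Con 3 (camera adjusted p = 0.850) and was 0.49 without Con 1. The interferon call ended without Combo 1 (0.07, camera adjusted p = 0.539), Con 2 (0.06, 0.480) or Con 1 (0.21, 0.0543), and its median was 0.31 without either Combo 2 or Con 3. The mitochondrial one ended without Con 1 (0.05, 0.388), Con 2 (0.14, 0.143) or Combo 1 (0.12, 0.10), and the median was 0.33 without Con 3.

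When QTP was added to radiation (Combo against IR), camera with the preset correlation called sterol and fatty acid lists higher, and 0 lists with an estimated correlation (lowest adjusted p = 0.400). Cholesterol biosynthesis genes had a median of 0.63, with 19 of 21 higher and 1 lower adjusted over the list alone (camera adjusted p = 4.08e-15, and adjusted p = 0.400 with an estimated correlation). DHCR7 went from 27.4 ± 3.92 FPKM in IR to 60.2 ± 11.2 in Combo (SD, n = 3; log2 change 1.10, SE 0.20), and HMGCS1 differed by 1.19 (SE 0.28). Fatty acid genes rose by 0.33 (9 adjusted over the list alone; camera adjusted p = 2.23e-09, and adjusted p = 0.400 with an estimated correlation) and cholesterol uptake genes by 0.30 (6 adjusted over the list alone; camera adjusted p = 1.20e-04, and adjusted p = 0.413 with an estimated correlation). The integrated stress response rose by 0.19 (4 adjusted over the list alone; camera adjusted p = 9.76e-05, and adjusted p = 0.400 with an estimated correlation), with ASNS, asparagine synthetase, at 0.61 (SE 0.13) and SLC7A11, a cystine transporter gene, at 0.59 (SE 0.13). CDKN1A differed by 0.02 (SE 0.11), and the p53 list was not called (-0.09, camera adjusted p = 0.101).

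Ribosomal protein genes fell by a median of 0.41 on the log2 scale, all 30 adjusted over the list alone (camera adjusted p = 4.31e-15, and adjusted p = 0.413 with an estimated correlation), and by 0.27 on it without IR 3, the library with the highest mitochondrial share. Respiratory chain genes fell by 0.29 on that scale (18 of 25 adjusted over the list alone; camera adjusted p = 2.00e-10, and adjusted p = 0.413 with an estimated correlation). Mitosis genes had a median of -0.31 (0 adjusted over the list alone; camera adjusted p = 1.50e-06, and adjusted p = 0.530 with an estimated correlation) and replication genes one of -0.22 (0 adjusted over the list alone; camera adjusted p = 1.19e-04, and adjusted p = 0.586 with an estimated correlation). NF-kB factors had 0.38 (camera adjusted p = 4.23e-04, and adjusted p = 0.413 with an estimated correlation), interferon-stimulated genes 0.23 (camera adjusted p = 0.0192, and adjusted p = 0.659 with an estimated correlation), NRF2 genes 0.08 (camera adjusted p = 0.0337, and adjusted p = 0.413 with an estimated correlation) and lysosome genes 0.05 (camera adjusted p = 0.0150, and adjusted p = 0.413 with an estimated correlation). Adjusted over the list alone, 3 NRF2 genes were higher and 1 lower, and 0 of the other 3 lists passed.

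In Combo against IR the count of single genes rested on 1 library: without IR 1, limma called 956 genes, 262 higher and 694 lower, against 0 with all libraries. Calls ended without IR 1 (NRF2 genes 0.11, camera adjusted p = 0.179; lysosome 0.03, 0.145), without Combo 1 (lysosome 0.02, 0.0713; interferon 0.10, 0.380) and without IR 2 (interferon 0.09, 0.332). Without Combo 3 the replication median was -0.12 and that of the integrated stress response 0.12, and without Combo 2 the interferon one was 0.35.

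When radiation was added to QTP (Combo against Rx), camera with the preset correlation called proliferation lists lower and p53 targets higher, and 0 lists with an estimated correlation (lowest adjusted p = 0.607). All 28 mitosis genes had a lower mean in Combo (median -0.40, 5 adjusted over the list alone; camera adjusted p = 1.57e-14, and adjusted p = 0.607 with an estimated correlation), with KIF11, a spindle motor gene, at -0.47 (SE 0.14). All 27 replication genes had one too (-0.30, 0 adjusted over the list alone; camera adjusted p = 5.48e-11, and adjusted p = 0.607 with an estimated correlation). The p53 targets rose by 0.11 (camera adjusted p = 3.18e-05, and adjusted p = 0.607 with an estimated correlation), with CDKN1A at 0.32 (SE 0.11) and TP53INP1, a stress-induced p53 target, at 0.36 (SE 0.09) and the only one adjusted over the list alone. Cholesterol biosynthesis was not called (median 0.00, camera adjusted p = 0.821).

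Ribosomal protein genes (-0.24; camera adjusted p = 4.15e-09, and adjusted p = 0.607 with an estimated correlation) and respiratory chain genes (-0.21; camera adjusted p = 7.26e-07, and adjusted p = 0.607 with an estimated correlation) were also lower in Combo than in Rx. So were recombination genes (-0.17; camera adjusted p = 0.0248, and adjusted p = 0.607 with an estimated correlation), while lysosome genes were higher (0.05; camera adjusted p = 0.00650, and adjusted p = 0.607 with an estimated correlation), with 0 genes of these 4 lists adjusted over the list alone. The recombination call turned at a mean of at least 5 FPKM (0.05, camera adjusted p = 0.632) and ended without Rx 1 (-0.10, camera adjusted p = 0.260), Rx 3 (-0.22, 0.0572), Combo 2 (-0.14, 0.0904) or Combo 3 (-0.11, 0.0723), and the lysosome call without Rx 3 (0.06, 0.187). Without Rx 2 camera called 17 lists in place of 7. Without Combo 2 the p53 median was 0.03 and the lysosome one 0.11, and without Combo 3 the replication one was -0.20.

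The interaction asks whether the effect of QTP differed between sham and irradiated cells. It was called by camera for ribosomal protein genes, with a median of -0.44 and 30 of 30 genes negative (adjusted p = 2.20e-14, and adjusted p = 0.874 with an estimated correlation), and for respiratory chain genes, with one of -0.24 and 23 of 25 negative (adjusted p = 1.24e-06, and adjusted p = 0.874 with an estimated correlation). No gene of either passed adjusted over the list alone, RPL11 being at -0.53 (SE 0.17) and ATP5PO, an ATP synthase subunit gene, at -0.50 (SE 0.17). Neither cholesterol biosynthesis (median 0.16, camera adjusted p = 0.109) nor mitosis genes (-0.07, 0.875) nor p53 targets (-0.14, 0.243) had an interaction past the threshold. Without IR 3 the respiratory median was -0.16. Camera called 5 lists without Con 3 and 4 without any 1 of Con 1, Rx 2, Rx 3 or Combo 1, in place of 2, and limma called 3 genes without IR 1 and 1 without Rx 3, in place of 0.

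Across the 13038 genes, the radiation effects with and without QTP, which share no library, had a Pearson r of -0.03 and a Spearman rho of -0.05, with 47.5% of genes having the same sign. Those of QTP with and without radiation had an r of 0.04 and a rho of 0.04, with 50.3% having the same sign. Genes are not independent replicates, and no p was computed across them. The first r was -0.22 without IR 1 and 0.23 without IR 3, and the second 0.14 without Rx 2 and -0.04 without Rx 3.

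Comparisons averaged over both arms of the other treatment were added after the data had been examined. Averaged over sham and irradiated cells, QTP changed 12 genes, 11 of them higher, all at an adjusted p of 0.0493 by limma; averaged over vehicle and QTP, radiation changed 0 genes (1109 at an unadjusted p under 0.05; 0 by limma voom). Of the 12, 4 make or modify sterols or fatty acids or carry sterols and were in the lists fixed in advance. DHCR7 (chromosome 11, 71428193 to 71452868) was at 30.9 ± 5.89 FPKM without QTP and 59.9 ± 13.1 with it (SD, n = 6), a log2 change of 0.93 (SE 0.14). STARD4 (chromosome 5, 111496033 to 111512590) differed by 0.58 (SE 0.08), FADS1 (chromosome 11, 61799625 to 61829318) by 0.56 (SE 0.08), and SC5D, a sterol desaturase gene (chromosome 11, 121292453 to 121308694), by 0.42 (SE 0.07).

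The other 8 were outside those lists. LPIN1, a phosphatidate phosphatase gene, rose by 0.68 (SE 0.10), ERG28, an endoplasmic reticulum protein of sterol synthesis, by 0.52 (SE 0.08), the retinol dehydrogenase gene RDH11 by 0.44 (SE 0.07), and IDH1, cytosolic isocitrate dehydrogenase, from 18.6 ± 1.55 to 25.5 ± 1.66 FPKM (SD, n = 6; 0.43, SE 0.05). PRXL2A rose by 0.43 (SE 0.07). The pseudogene HSD17B7P2 (0.45, SE 0.07) can share reads with HSD17B7, and MIR635 (0.92, SE 0.14) is a 98-base model inside WIPI1 with 5 to 23 reads per library. GAMT, which makes creatine, fell by 0.34 on the log2 scale (SE 0.05). The count was 0 after rescaling to TPM or by the median of ratios, and lay between 0 and 18 with 1 library left out. It was 0 without any 1 of Con 1, Con 2, Con 3, IR 2, IR 3, Rx 3 or Combo 3, 1 without Rx 2 or Combo 2 and 2 without Combo 1, and 18 without Rx 1.

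A test with 1 mean per library and list, permuted within the arms of the other treatment, was also added after the data had been examined. It has 400 arrangements, and its smallest p is 0.005. Of 46 tests, 6 reached that two-sided exact permutation p, with an adjusted p of 0.0383. Reaching it means that all treated libraries lay beyond the untreated ones in both arms, so that order is not further support. The adjusted p depends on how many tests tied at the smallest p. With QTP the list mean was higher by 0.53 for cholesterol biosynthesis, 0.30 for cholesterol uptake and 0.23 for the integrated stress response. It was higher by 0.13 for NRF2 genes and 0.12 for lysosome and autophagy genes, and with radiation by 0.16 for p53 targets. The order was narrow for p53 targets, with Combo 3 at -0.042 and Rx 1 at -0.053, and Combo 3 lay below Con 3 (-0.025). It was narrow too for lysosome genes with QTP, with Rx 3 at -0.039 and Con 1 at -0.047. Just outside the threshold were fatty acid synthesis with QTP (0.40, exact permutation p = 0.01, adjusted p = 0.0575), lysosome genes with radiation (0.12, 0.01, 0.0575), and mitosis genes (-0.39, 0.015, 0.069), recombination genes (-0.19, 0.015, 0.069) and replication genes with radiation (-0.26, 0.02, 0.0767). NF-kB and secreted factors with QTP stood at the last of these values too (0.38, exact permutation p = 0.02, adjusted p = 0.0767). After rescaling to TPM the adjusted p of the 6 was 0.138 to 0.184, and with 1 library left out its highest values were 0.0657 to 0.115. Of the results with 1 library left out, 36 kept the call and 36 lost it, while the change in cholesterol biosynthesis lay between 0.45 and 0.60 and that in p53 targets between 0.14 and 0.18.

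**Figure D3:**
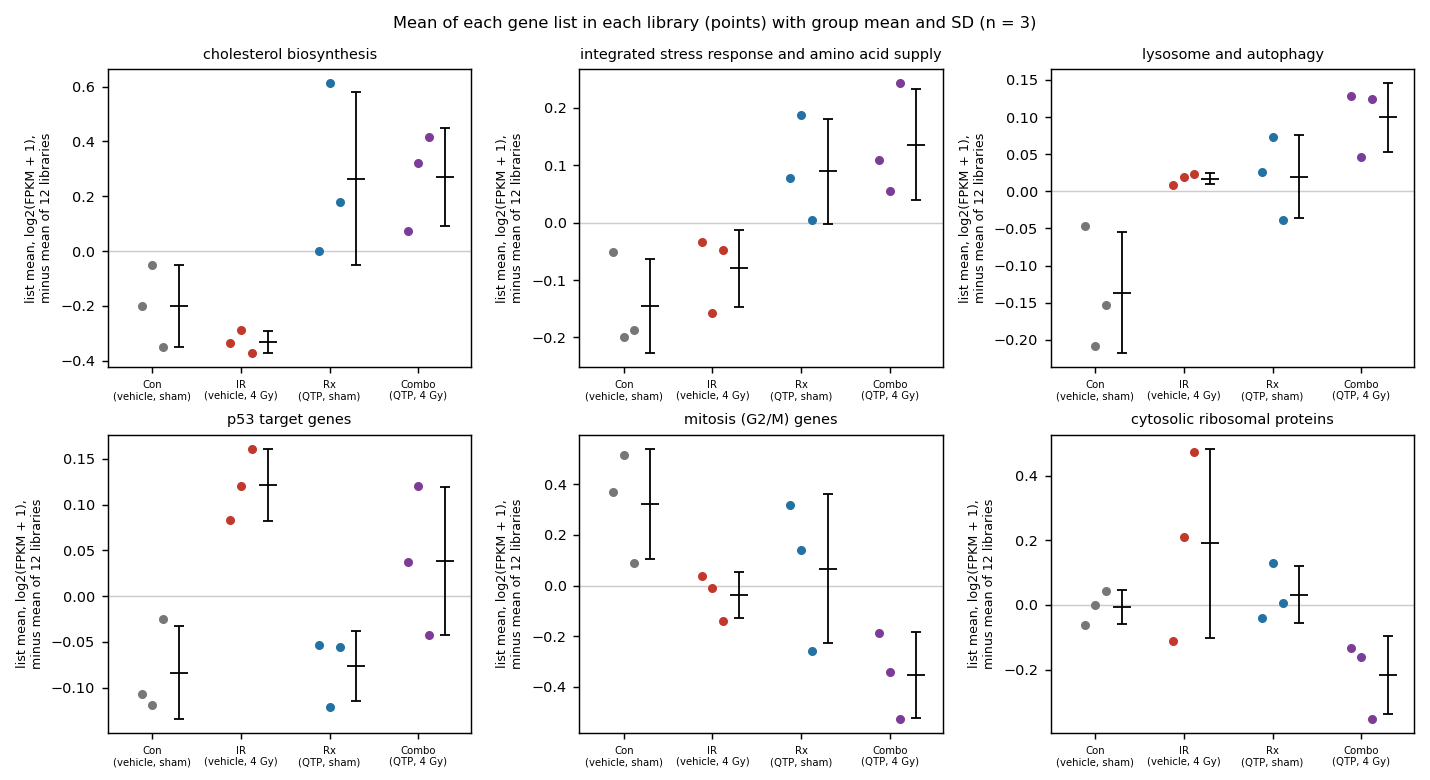
Mean of 6 gene lists in each library (points), on the log2(FPKM + 1) scale less the mean of all 12 libraries, with the group mean and SD (black, n = 3). All Rx and Combo libraries lie above all Con and IR libraries for cholesterol biosynthesis, and the 3 Combo libraries lie lowest for ribosomal protein genes.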

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

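Of the tests in this part, the one without IR 3, the one of the order of the Combo libraries and the counts over other splits were chosen only after the result was seen. Camera's test of the interaction, whether QTP acted differently in sham and irradiated cells, called 2 lists with the preset correlation: cytosolic ribosomal proteins (median -0.442807 on the log2 scale) and the nuclear-encoded respiratory chain (-0.244952). Neither was called with an estimated correlation (camera adjusted p = 0.874 for both). The list means were 0.19 in IR, 0.03 in Rx, -0.01 in Con and -0.22 in Combo for ribosomal proteins, relative to the mean of the 12 libraries.

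Without IR 3 the mean interaction of the ribosomal list was -0.30 (SE 0.15), which argues only weakly against IR 3 as the whole cause. With all libraries it was -0.44 (SE 0.19, 8 degrees of freedom), and without both IR 3 and Combo 3 it was -0.23. The respiratory chain list, to which this test was not applied, had -0.24 with all libraries and -0.11 without both. The rule that the mean must lie below -0.1 by more than its SE was set after these values were seen, and so small a margin does not exclude IR 3. After gene length and GC content were removed from each library, the ribosomal list had a mean of -0.37 (SE 0.17), which by that rule argues only weakly against them. All 3 Combo libraries lay below the 9 others in the ribosomal list mean, but narrowly, with Combo 1 at -0.13 and IR 1 at -0.11. An effect of the combination on every library would give this order. That effect stays open as a hypothesis found and tested on the same data. The list test was not repeated after rescaling to TPM or by quantiles. Of 100 splits of the 12 libraries, 97 gave at least the 2 lists called (highest other 15). These splits shuffled all 12 libraries over the 4 groups, so effects of QTP or radiation alone can enter the shuffled interaction. The share therefore cannot decide on chance, which is not excluded. For single genes the real count was 0, which all 100 splits reach by construction (highest other 3), so that count says nothing about chance. Members of these lists move together, with an estimated correlation of 0.93 for ribosomal proteins.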

How the results depend on the processing

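The averaged comparisons, voom, the protein-coding fit, the fit without IR 3 and Combo 3, and the list means per library were chosen after the results were seen. The cause of each change below was not tested. With an estimated correlation, camera called 0 lists in all 6 planned and both averaged comparisons. Without a filter on low values, limma called 5 genes in IR against Con, 1 in Rx against Con, 5 in Combo against Con, 6 in Combo against IR, 4 in Combo against Rx and 6 in the interaction (0 each with the filter), 6 with QTP averaged (12) and 5 with radiation averaged (0). At a mean of at least 5 FPKM it called 24 with QTP averaged, camera called 4 interaction lists (2), and the recombination list in Combo against Rx turned to 0.0487 (camera adjusted p = 0.632). That filter also ended the recombination call in IR against Con (-0.07, camera adjusted p = 0.0503), Rx against Con (-0.08, 0.0582), Combo against Con (-0.03, 0.597) and with radiation averaged (-0.0015, 0.476), and the mesenchymal one with radiation averaged (0.12, 0.10). Leaving out IR 3 and Combo 3 ended the ribosomal call in IR against Con (0.06, camera adjusted p = 0.0581), the mesothelial one in Combo against Con (-0.21, 0.0686) and the recombination one in Combo against Rx (-0.11, 0.122). With QTP averaged limma called 0 genes after TPM or median-of-ratios rescaling, without a variance trend, or without IR 3 and Combo 3, 23 after quantile normalization, 30 with protein-coding genes alone and 33 with voom. Library quality weights gave 1013 genes in IR against Con, 178 in Combo against Con, 4496 in Combo against IR, 777 with QTP averaged and 359 with radiation averaged. Their estimation stopped before it converged and gave IR 2 a weight of 17.4, against 0.295 to 1.62 for the others.

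The labels do not say that equal numbers mark a pair, and 11 of 18 same-numbered pairs deviated together (r over 0.1; mean 0.12, from -0.21 to 0.35), so the libraries were not taken as paired. Differently numbered pairs had a mean r of -0.06, which largely follows from the same-numbered value, since deviations from a group mean sum to 0. As a hint from the data, 11 of 12 libraries correlated best with those of their own number. A link between equal numbers is therefore not excluded, and the main fits, the permutations and the splits ignore it. With the number as a replicate block limma called 90 genes in Combo against Con (23 higher, 67 lower) and 3 with radiation averaged (0 higher, 3 lower), and the counts of lists stayed within 1.5 times. The block ended 1 call, of respiratory chain genes with radiation averaged (-0.07, camera adjusted p = 0.0591). Voom with the replicate block called 1 in IR against Con, 301 in Combo against Con, 36 in Combo against IR, 87 with QTP averaged and 79 with radiation averaged.

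With 1 library left out, limma called 0 to 3 genes in IR against Con, 0 to 956 in Combo against IR (956 without IR 1), 0 to 3 in the interaction, 0 to 18 with QTP averaged and 0 to 1 with radiation averaged, and 0 in the others. Camera called 5 to 17 lists in Combo against Rx and 2 to 5 in the interaction. The correlation of radiation effects ran from -0.22 to 0.23 and that of QTP effects from -0.04 to 0.14. The hypoxia list in Combo against Con ran from -0.0382 (without Con 3, camera adjusted p = 0.850) to 0.49. Over all called lists and left-out libraries, 961 results kept the call, 46 lost it and 1 reversed. List means per library kept their direction under every scaling and filter run, cholesterol biosynthesis with QTP lying between 0.53 and 0.57 (0.45 to 0.60 with 1 library left out). With 1 library left out 36 list mean results kept the call and 36 lost it. After TPM rescaling none of the 6 passed the threshold, and lysosome genes with QTP also missed it at a mean of at least 5 FPKM and after median-of-ratios rescaling. Depth limits low genes most, since 1 FPKM of a 1 kb gene rests on 13.3 to 19.1 reads.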

Other observations

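The tests of scaling, of the mitochondrial share and of depth for the hypoxia list and the counts over other splits were chosen only after the result was seen. Averaged over vehicle and QTP cells, radiation lowered the mitosis list by a median of 0.38 on the log2 scale, 27 of 28 genes being lower adjusted over the list alone (camera adjusted p = 1.60e-26; adjusted p = 0.202 with an estimated correlation). Replication genes had a median of -0.27, with 17 of 27 adjusted over the list alone (camera adjusted p = 4.44e-17; adjusted p = 0.209 with an estimated correlation), and recombination genes one of -0.20, with 9 of 16 (camera adjusted p = 1.07e-06; adjusted p = 0.202 with an estimated correlation). The recombination call ended at a mean of at least 5 FPKM (-0.0015, camera adjusted p = 0.476). The p53 targets rose by 0.15, with 29 of 30 higher and 3 adjusted over the list alone (camera adjusted p = 5.46e-15; adjusted p = 0.0785 with an estimated correlation). CDKN1A differed by 0.41 (SE 0.08), TP53INP1 by 0.28 (SE 0.06) and BTG2 by 0.30 (SE 0.07). Mesenchymal and matrix genes, not called in the planned comparisons, were higher by a median of 0.16 (camera adjusted p = 0.0179, and adjusted p = 0.453 with an estimated correlation). That call ended without Combo 1 (0.12, camera adjusted p = 0.0640), Con 3 (0.15, 0.0917), IR 1 (0.10, 0.146) or Rx 3 (0.16, 0.0997), and at a mean of at least 5 FPKM (0.12, 0.10).

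Several hypoxia and glycolysis genes differed widely between libraries of 1 group, and the examples CA9, LDHA and PFKFB3 were chosen after their values were seen. In Con, NDRG1, a hypoxia-induced gene, was at 42.1, 13.6 and 4.34 FPKM, CA9, a carbonic anhydrase gene induced by HIF, at 19.0, 12.1 and 1.49, and the glycolysis gene LDHA at 209, 154 and 86.9. PFKFB3 of the same list was at 8.40, 8.72 and 7.94. The list mean spanned 1.40 on the log2 scale (2.64-fold) across the Con libraries.

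The libraries high in this list had a lower mitochondrial read share within groups (12 libraries, Pearson r -0.73, permutation p = 0.00772, adjusted p = 0.0154; Spearman rho -0.78, permutation p = 0.0154, adjusted p = 0.0309; r -0.67 without the 2 farthest libraries; 2 relations tested). The order held in Con, IR and Rx but not in Combo. There Combo 3 had a list mean of 0.27 and a share of 8.98%, against 0.07 and 8.06% in Combo 2. A candidate explanation is that culture conditions such as oxygen or cell density differed between flasks, for which the labels give no measure. Sequencing depth cannot be told apart from this: r was 0.73 with the recovered reads (permutation p = 0.106, adjusted p = 0.106) and Spearman rho 0.76 (permutation p = 0.0378, adjusted p = 0.0378). Without the 2 farthest libraries r was 0.37, so that relation rests largely on them. A p that misses the threshold does not show that there is no relation, and the rank test passed it.

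Cholesterol biosynthesis genes were higher with QTP by a list mean of 0.53. This difference was 0.532 after all libraries were thinned to 13188257 reads. Thinning leaves the expected FPKM of genes with many reads as it was, so it could not decide on depth as the cause. Scaling is argued against by a median of -0.00482 over all tested genes, and gene length and GC content by 0.545 after both were removed. An effect of QTP on sterol gene expression in both arms may be taken as a hypothesis, found and tested on the same data. Shared handling of the QTP flasks was not tested, and depth stays open.

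Other splits of the same libraries bear on chance. Of 100 splits within arms, only the real one gave as many as the 12 genes called with QTP averaged (1 of 100, highest other 1). The share is under 0.05, but the comparison and the splits were chosen after the result was seen. Chance is therefore not excluded for that count. These splits were drawn again after a first count had been seen, to take out repeated and mirrored ones, which lowered the count of splits by 1. The 12 genes lie close to the threshold (limma adjusted p = 0.0493), and their number fell to 0 without any 1 of 7 libraries and after TPM or median-of-ratios rescaling. Nor is chance excluded for the lists with QTP averaged, where 12 of 100 gave 14 or more (highest other 15). The same holds with radiation averaged, where 42 of 100 gave 9 or more lists (highest other 16). For single genes with radiation averaged the real count was 0, which 100 of 100 splits reach by construction, so it says nothing about chance. A split that gave 19 genes may point to a structure of the libraries other than radiation, or to chance, and neither was tested. The correlations between effects were reached by 55 of 100 splits for radiation (highest other 0.44) and 46 of 100 for QTP (highest other 0.30).

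A split of 3 against 3 has 10 arrangements, too few for a share under 0.05. As many lists were called by 5 of 10 splits in IR against Con (9 real, highest other 12), 1 of 10 in Rx against Con (13, 12), 1 of 10 in Combo against Con (18, 12), 1 of 10 in Combo against IR (12, 10) and 8 of 10 in Combo against Rx (7, 13). For single genes the real count was 0 in each, reached by 10 of 10 splits by construction, with a highest other of 0, 1, 2, 0 and 0.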
